A study of Mus musculus with 6 samples.

How the data were processed

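Total RNA from whole mouse knees was measured on Illumina bead arrays, per the labels' protocols. The RNA was extracted with Trizol, cleaned up with a DNase I step and checked on a Bioanalyser, and amplified, biotin-labelled cRNA was hybridised, so that each array has 1 colour. The array design, the scanner software and their versions are not given in the sources used here. The 6 samples were 3 wild-type and 3 Mapk9 knockout knees on the C57BL6 background, from mice 12 weeks old, taken 6 hours after the injury. Groups and replicate numbers come from the sample titles. The labels do not say whether the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Uninjured knees were not analysed here, so no value is a change caused by the injury.

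The deposited non-normalized table gives, per the file headers, an average bead intensity and a detection p-value for each of 45281 probes on each array. The intensities are linear, differ in median between arrays and have no value at or below 0, and no between-array normalization of these values is recorded. The deposited detection p-value compares a probe with the negative control beads of its own array and runs in steps of 1 in 936. The authors' normalized table holds log2 values for 21004 probes, including all 17258 probes tested here. How the authors made these log2 values is not given in the sources used here. Each of its columns has a rank correlation of 1 with the intensity of the same sample. Its sorted columns differ by up to 1.01, so the arrays are not equal in distribution over these 21004 probes. This does not tell whether they were made equal over all 45281 probes. The deposited log2 values have medians of 7.66, 7.65 and 7.67 in wild-type replicates 1, 2 and 3 and 7.72, 7.44 and 7.60 in knockout replicates 1, 2 and 3. The value table of the series matrix equals the authors' normalized table, with a largest difference of 0. Of the probes, 40 carried symbols that a spreadsheet program had turned into dates; 34 were restored from the probe's own definition and 6 were left unnamed. Gene symbols, probe identifiers and probe coordinates are those of the authors' tables, which name no genome build, and many symbols are old. The exon or UTR under a probe was not analysed here, since no genome of the build was at hand.

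Intensities were background-corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, with the background taken from the detection p-values, an offset of 16 and quantile normalization between arrays. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were tested, 17258 probes for 12760 gene symbols. Genotypes were compared with lmFit and eBayes of limma over all 6 samples, two-sided, at a Benjamini-Hochberg adjusted p under 0.05. A gene was counted once by its symbol, and where its probes disagree the text gives each. Differences are knockout minus wild-type on the log2 scale, with the SE of the fit, and group values are mean ± SD over 3 arrays. A probe not detected on any array of 1 genotype has only a bound there. Its fold is given as "at least", as the bright group's mean against the dim group's mean of the higher of the probe's own value and the lowest detected signal of each array.

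By the check set for this, the replicate numbers counted as pairing the samples. The deviations from the genotype mean of same-numbered wild-type and knockout samples correlated across probes at r = 0.610, 0.181 and 0.595 for numbers 1, 2 and 3, all over the limit of 0.1. Knockout replicate 2 correlated better with wild-type replicate 3 (r = 0.327) than with its own number. Deviations within a genotype cancel out, so these correlations are not independent, and the check does not show that the samples were paired by design. The labels do not say what the numbers share, although the sample codes of a same-numbered pair carry its digit. The fit without a block was set as the principal one, and the fit with the replicate number as a fixed block is printed beside each result whose call it changes. With the number as a random block the consensus correlation was 0.457.

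Gene lists for tissues, cell types and pathways of the injured joint, 41 in all, were written together with the design, the alternatives and the rule for named genes before the data were examined. Each list with at least 5 measured members, 39 in all, was tested with camera of limma at a preset correlation between genes of 0.01, using 1 probe per gene (the tested probe with the highest mean). The skin epithelium list (4 measured members) and the sex-linked list (3 measured members) were too small for the test. A called list is one with a Benjamini-Hochberg adjusted p under 0.05 over the 39 lists. For each list the text also gives how many members changed over all probes tested and how many adjusted over the list alone. The named genes are Mapk9, up to 15 genes per direction with the largest changes past the threshold and no overlap between genotypes (filled to 10 per direction by the smallest p), up to 4 members of each described list by the smallest p, and 14 genes of JNK signalling, inflammation and cartilage written down in advance. Adamts5 had no probe under that symbol in the tables used and was not analysed here. The text gives only some of these list members, and the results of 3 that the rule also names are not reported here in text or tables.

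The steps were tested on simulated data with noise of the size seen on these 6 arrays, 17258 probes and 100 probes changed at each size. The noise was drawn independently for each probe. The fit without a block recovered 12% of changes of 1 and 61% of changes of 2 on the log2 scale, with 2 false calls among 75. The fit with the replicate block recovered 0% and 52%, with 1 false call among 53. Recovery depends on how many probes change, since the adjustment is stricter where few do. The shares of the block fit therefore do not carry over to these data, where 4826 of the 17258 probes passed with the block. Camera called the simulated shifted list and 0 of 200 unchanged lists. These lists were random and free of correlation between genes, so this does not show how often camera errs where list members vary together.

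The alternatives were no background correction, an offset of 50, scaling to the median in place of quantile normalization, the authors' log2 values and the series matrix values, the fixed and random replicate block, a variance trend with robust eBayes, array weights, leaving out each sample in turn, no filter on dim probes, a filter of detection p under 0.01 on all 6 arrays, a test against a fold of 1.5, 1 probe per gene, camera with an estimated correlation, fry, and list values averaged over probes. Chosen after seeing the data were a tissue score as a covariate, the block with the authors' table, and repeats of the block fit under other settings. The tissue score of a sample is the mean of the skeletal muscle list minus the mean of the erythroid, neutrophil and B cell lists. The order of genes along chromosomes came from a gene table of assembly GRCm38.p6, of which no coordinate is printed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.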

Results

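The series compared injured knees of wild-type mice with those of mice lacking Mapk9, the gene of the stress-activated kinase JNK2. All knees were taken 6 hours after destabilization of the medial meniscus, an operation on the knee that is widely used as a mouse model of osteoarthritis. The question was which transcripts of the freshly injured joint differ when JNK2 is absent. Whole knees hold cartilage, bone, marrow, synovium, fat and muscle, and each array measured their mixed RNA. There were 3 samples of each genotype, with 1 array per sample. Mean bead intensity was 587, 456 and 505 in wild-type replicates 1, 2 and 3 and 611, 420 and 550 in knockout replicates 1, 2 and 3. The number of probes detected at p under 0.05 was 17248, 16908 and 17188 in the wild-type samples and 17792, 15374 and 15985 in the knockout samples, of 45281 probes. With 3 arrays per genotype, the number of arrays limits the precision.

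Mapk9 itself was lower in every knockout sample than in every wild-type sample. Probe ILMN_2716527 (chromosome 11, 49687779 to 49687828, build not given in the sources used here) read log2 signals of 7.46, 7.18 and 7.11 in wild-type samples. In the knockout samples it read 5.01, 4.99 and 5.11 and was not detected above background on any array, so that it was at least 2.24-fold lower there. The fit gave a difference of −2.21 (SE 0.18, adjusted p = 0.0140 in limma), which has no exact size for that reason. Probe ILMN_2591066 (chromosome 11, 49699460 to 49699509) read 10.73, 10.42 and 10.47 in wild-type and 8.65, 9.14 and 8.83 in knockout samples, a difference of −1.67 (SE 0.21). Its adjusted p was 0.0654 without a block and 0.00475 with the replicate block. Leaving out wild-type replicate 1, 2 or 3 or knockout replicate 2 or 3 moved the adjusted p of ILMN_2716527 to 0.0761, 0.158, 0.0984, 0.112 and 0.118, and leaving out knockout replicate 1 moved that of ILMN_2591066 to 0.00761. The other 2 probes of Mapk9 were detected on no array. Which part of the gene the knockout removes is not given in the sources used here, so it is open whether these probes lie inside it.

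Besides Mapk9, 4 genes fell and 2 rose in knockout knees without a block. Nnmt, which methylates nicotinamide, read 11.03 ± 0.86 in wild-type and 5.18 ± 0.15 in knockout samples (n = 3 each) with probe ILMN_2544305. It was undetected in all knockout samples and at least 30.8-fold lower (adjusted p = 0.00445), while its other 2 detected probes differed by −1.44 and −1.54. Adamts9, a protease of versican and aggrecan, read 9.73 ± 0.55 against 5.07 ± 0.17, at least 12.6-fold lower with the knockout signal undetected (adjusted p = 0.00445), and had no second detected probe. Sparc, a collagen-binding matrix protein of bone, fell by 3.57 (SE 0.35, adjusted p = 0.0368) with probe ILMN_1243212, from 10.09 ± 0.46 to 6.52 ± 0.58, whereas 2 brighter probes of Sparc differed by −0.33 and −0.21. The unnamed transcript LOC380706, also with a single detected probe, was at least 5.09-fold lower (8.43 ± 0.31 against 5.28 ± 0.05, adjusted p = 0.00445). Myh8, the perinatal myosin heavy chain, was detected only in knockout samples with probe ILMN_1223735 and was at least 4.23-fold higher (5.69 ± 0.28 against 8.03 ± 0.36, adjusted p = 0.0495), and its second probe differed by 0.37. Wdfy1, an adaptor of endosomal Toll-like receptors, rose 3.49-fold, from 8.02 ± 0.20 to 9.83 ± 0.11 (difference 1.80, SE 0.19, adjusted p = 0.0495). All 7 genes also passed with the replicate block.

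Leaving out single arrays ended calls of each of these 6 genes, although the fitted differences, which have no exact size where a genotype was undetected, stayed about as large, at −6.32 to −5.48 for Nnmt, −4.98 to −4.48 for Adamts9, −3.29 to −2.99 for LOC380706, −3.88 to −3.31 for Sparc, 2.15 to 2.51 for Myh8 and 1.69 to 1.87 for Wdfy1. Without knockout replicate 2, Nnmt, Adamts9 and LOC380706 had an adjusted p of 0.0599 and Sparc, Myh8 and Wdfy1 one of 0.253. Without wild-type replicate 2, Adamts9 (0.0507), LOC380706 (0.0672), and Sparc, Myh8 and Wdfy1 (0.263 each) did not pass. Sparc was also lost without wild-type replicate 1 (0.0761) or 3 (0.106). Myh8 and Wdfy1 were lost without wild-type replicate 1 (0.154 and 0.140), wild-type replicate 3 (0.106 each) and knockout replicate 3 (0.290 and 0.303). Myh8 also did not pass with the authors' log2 values (difference 2.35, adjusted p = 0.0556), no background correction (1.20, 0.0725) or the tissue score as a covariate (1.78, 0.197), and Wdfy1 with the authors' log2 values (1.70, 0.0556), median scaling (1.66, 0.0662), the stricter detection filter (1.80, 0.0681) or the tissue score (2.05, 0.0839). Nnmt, Adamts9, Sparc and LOC380706 passed with the tissue score (adjusted p = 0.0259, 0.0136, 0.0136 and 0.0259). Testing the brightest probe of each gene ended the calls of Myh8 and Wdfy1 (0.0604 each) and left these probes of Nnmt and Sparc untested. Against a fold of 1.5 Sparc (0.0709), Myh8 (0.184) and Wdfy1 (0.257) did not pass. With dim probes kept in the test, Adamts9 (0.0595), Nnmt and Wdfy1 (0.0770 each) and Sparc and Myh8 (0.127 each) did not pass.

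**Figure D1:**
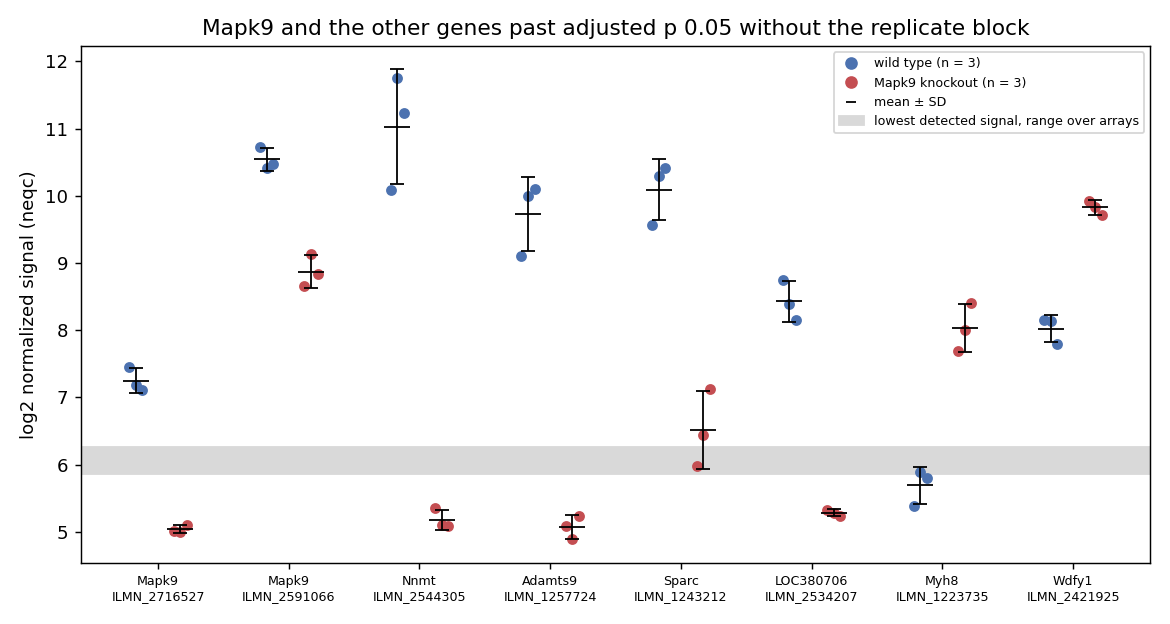
Log2 normalized signal of 2 Mapk9 probes and of the other 6 genes past adjusted p 0.05 without a block, with 1 point per sample (blue wild-type, red Mapk9 knockout), mean ± SD bars and n = 3 per genotype. The grey band spans the lowest detected signal of the arrays, and the knockout points of Nnmt, Adamts9, LOC380706 and Mapk9 ILMN_2716527 lie below it.

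In all, 7 genes passed without a block (2 higher, 5 lower) and 3888 genes with the replicate block (1865 higher, 2008 lower and 15 with probes in both directions). Of the 3888, 1729 also differed by over 2-fold on some probe. With the block 4826 of the 17258 probes passed (28.0%). Counts of members past the block threshold in the groups below are to be read against that share, and a smaller share is no sign of a shift. Without a block, 4922 of the 17258 probes had an unadjusted p under 0.05 in limma and 1160 an adjusted p under 0.10 (840 higher, 320 lower). Of all probes tested, 5246 (30.4%) did not overlap between genotypes. Chance alone gives 10% on average over splits, but probes that vary together can give far more in a single split. No other split was counted for this. The next genes in line did not pass without a block (adjusted p from 0.0542 to 0.0738) and passed with it (adjusted p from 0.00415 to 0.00433). Among the higher ones, the muscle spring protein gene Ttn differed by 2.22, the potassium channel gene Kcnc1 by 2.19, the ubiquitin ligase gene Mid1 by 1.66 and the nuclear receptor gene Esrrb by 1.84, although a second Esrrb probe differed by 0.02. AU040829 and 1300013J15Rik differed by 2.04 and 1.91, and the nucleic acid-binding gene Ybx2 and C130017I15Rik, undetected in all wild-type samples, were at least 4.06-fold and 3.64-fold higher. Among the lower ones, Kif23, a kinesin of cell division, differed by −4.09 on one probe and −1.88 on another. Ranbp3l differed by −1.66 and 4732429D16Rik by −1.91, while 4933427D14Rik and an immunoglobulin kappa variable segment, undetected in all knockout samples, were at least 1.44-fold and 3.12-fold lower. Of the 16 genes with a known chromosome among those past the threshold or next in line, 7 lie on chromosome 11 with Mapk9, namely Sparc, Myh8, Ybx2, AU040829, 1300013J15Rik, 4732429D16Rik and 4933427D14Rik. The count without a block was 3, 1 and 3 genes without wild-type replicates 1, 2 and 3, and 4698, 0 and 4 genes without knockout replicates 1, 2 and 3. For the count of 0, limma gave 2625 probes at an unadjusted p under 0.05.

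The arrays did not part cleanly by genotype. The first principal component held 73.0% of the variance and placed the wild-type samples at −71.5, −37.0 and −15.3 and the knockout samples at −14.9, 72.9 and 65.9. Knockout replicate 1 correlated at r = 0.972 across probes with wild-type replicate 2 and at 0.923 with knockout replicate 2, while knockout replicates 2 and 3 correlated at 0.981. The tissue score, the mean of muscle markers minus the mean of erythroid, neutrophil and B cell markers, was 1.28, 2.15 and 2.55 in wild-type replicates 1, 2 and 3, 2.63 in knockout replicate 1, and over 4 in knockout replicates 2 and 3 (4.13 in replicate 3). The score did not overlap between genotypes, so whatever it follows and genotype cannot be told apart in the gene groups described from here on. Whether it follows shares of tissue is not settled.

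Among genes of joint injury written down in advance, none passed without a block, and 4 passed with it, where 28.0% of all probes passed. The aggrecanase gene Adamts4 fell by 1.14 (SE 0.34, adjusted p = 0.110 without and 0.0233 with the block), from 8.40 ± 0.71 to 7.25 ± 0.03. Il1b, the gene of the inflammatory cytokine interleukin 1 beta, fell by 1.06 (SE 0.32, adjusted p = 0.113 and 0.0310). The AP-1 transcription factor genes went apart, as Fos fell by 0.72 (SE 0.20, adjusted p = 0.104 and 0.0222) and Jun rose by 0.53 (SE 0.31, adjusted p = 0.279 and 0.0498). Ccl2, a monocyte-attracting chemokine gene, differed by −0.78 (SE 0.59, adjusted p = 0.386 and 0.188). The collagenase gene Mmp13 differed by −0.46 to 0.12 over 3 probes and the stromelysin gene Mmp3 by −0.05 to 0.32 over 3 probes. Mapk8, the gene of JNK1, differed by 0.05, 0.11 and 0.61 on its 3 probes, and 2 of these and 1 Mmp3 probe turned negative with median scaling. The cartilage matrix genes Acan (−0.29 and −0.37) and Col2a1 (−0.49, −0.55 and −0.52) were lower on every probe without passing either fit. Il6 was detected in 2 wild-type samples (replicates 2 and 3) and in 0 knockout samples, and Mapk10 and Ptgs2 were detected in none.

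The muscle, mitochondrial and clock lists were higher in knockout knees in camera at its preset correlation. Of 27 skeletal muscle markers, 25 were higher, with a median difference of 0.56 (camera adjusted p = 7.78e-05, and adjusted p = 0.699 with an estimated correlation). With the replicate block 12 of them rose, 0 fell and 15 did not pass, among the 12 the sarcomere genes Ttn (1.71 on its brightest probe) and Neb (2.10), the calcium store gene Casq1 (1.64) and the Z-disc gene Myot (1.55). Of 32 genes of oxidative phosphorylation, the mitochondrial respiratory chain, 31 were higher, with a median of 0.52 (adjusted p = 4.24e-08, and adjusted p = 0.699 with an estimated correlation). With the block 14 rose and 18 did not pass, and examples were Sdhc (0.80), Cyc1 (0.78) and Ndufa9 (0.71). All 14 circadian clock genes were higher, with a median of 0.86 (adjusted p = 0.000189, and adjusted p = 0.699 with an estimated correlation), and with the block 9 rose, such as the nuclear receptor gene Rora (1.12), the deubiquitinase gene Usp2 (1.52) and the repressor gene Gm129 (1.22). Without a block 0 members of these 3 lists passed over all probes, while adjusted over the list alone 7, 11 and 3 rose without a block and 13, 20 and 11 with it. The means of the muscle list were 12.12, 12.55 and 12.73 in wild-type and 12.90, 13.30 and 13.29 in knockout samples, and all 3 lists were higher in knockout in 3 of 3 same-numbered pairs. With the tissue score as a covariate the oxidative phosphorylation and clock lists did not pass (adjusted p = 0.277 and 0.995).

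The lists of dividing cells and of blood cells were lower in knockout knees in camera at its preset correlation. These lists do not tell blood cells of the marrow from those elsewhere in the knee. All 23 cell cycle genes were lower, with a median of −1.25 (camera adjusted p = 2.36e-06, and adjusted p = 0.699 with an estimated correlation). With the block 21 fell, among them the mitotic kinase gene Plk1 (−1.55), the spindle motor gene Kif11 (−1.44), and Rrm2 (−1.22) and Mcm7 (−0.72) of DNA synthesis. The neutrophil list had a median of −1.10 over 22 genes (adjusted p = 5.44e-06), the erythroid list −0.93 over 22 (0.000786), the B cell list −1.09 over 14 (0.00381) and the mast cell and eosinophil list −1.10 over 11 (0.0125). Each of these 4 lists had adjusted p = 0.699 with an estimated correlation, and each was lower in knockout in 3 of 3 pairs. Knockout replicate 1 lay within the wild-type range in the cell cycle (10.20 against 9.87 to 10.94), erythroid (10.55 against 10.51 to 11.14) and B cell lists (8.52 against 8.28 to 9.27), and knockout replicates 2 and 3 lay lowest in all 5 lists (8.51 and 8.62 for cell cycle). With the block 14 neutrophil genes fell, such as Il8rb (−1.51) and Csf3r (−0.97), receptors for a chemokine and for G-CSF, and Retnlg (−1.27). Erythroid genes fell in 15 cases, such as the red cell membrane and nuclear factor genes Spna1 (−0.77), Gata1 (−1.60) and Hemgn (−1.93). Of B cell genes 9 fell, such as Cd79b (−1.54) of the antigen receptor, Faim3 (−1.71) and Blk (−1.38), and of eosinophil granule and mast cell genes 6 fell, such as Prg3 (−2.67), Epx (−2.37), Ear2 (−1.57) and Hdc (−1.29). Over all probes without a block 0 members of these 5 lists passed, and adjusted over the list alone 0, 2, 10, 0 and 5 fell without a block and 23, 19, 17, 9 and 6 with it, in the order cell cycle, neutrophil, erythroid, B cell and mast cell. With the tissue score as a covariate the mast cell list did not pass (adjusted p = 0.191) and the cell cycle list turned to higher (0.000241).

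The most abundant markers of these tissues read near the top of the range of the arrays, where a change may not show. The haemoglobin genes Hba-a1 (14.14 ± 0.03 against 14.23 ± 0.02) and Hbb-b1 (14.21 ± 0.04 against 14.23 ± 0.05), the neutrophil gene S100a8 (13.78 ± 0.06 against 13.84 ± 0.07) and the muscle genes Ckm (13.77 ± 0.11 against 13.87 ± 0.06) and Acta1 (13.80 ± 0.07 against 13.84 ± 0.06) differed by 0.02 to 0.10. Among erythroid genes the membrane anchor gene Ank1 (0.62) was higher past the threshold adjusted over the list alone, against the direction of its list. The 20 monocyte and macrophage markers fell as a list (median −0.52, adjusted p = 0.00441, and adjusted p = 0.699 with an estimated correlation), with 3 members past the threshold with the block, the scavenger and mannose receptor genes Cd68 (−0.74) and Mrc1 (−0.63) and the complement gene C1qa (−0.66). None of them passed adjusted over the list alone in either fit, and knockout replicate 1 (10.06) lay among the wild-type samples (9.91 to 10.10). T and NK cell markers (13 genes, median −0.58) did not pass without a block (adjusted p = 0.0829) and fell with it (adjusted p = 0.0455, and adjusted p = 0.903 with an estimated correlation). The T and NK list means were 8.31, 7.83 and 7.44 in wild-type and 8.48, 6.42 and 6.72 in knockout samples, so knockout replicate 1 was the highest of all 6 and 1 of 3 pairs went the other way. With the block 4 of these markers fell, among them the cytotoxic granule gene Nkg7 (−1.77) and the interleukin 7 receptor gene Il7r (−0.92), and 6 adjusted over the list alone. Without wild-type replicate 3 or knockout replicate 1 the T and NK list passed without a block too (adjusted p = 0.0481 and 0.00172). With the tissue score as a covariate the monocyte list did not pass (0.942) and the T and NK list turned to higher (2.07e-05).

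**Figure D2:**
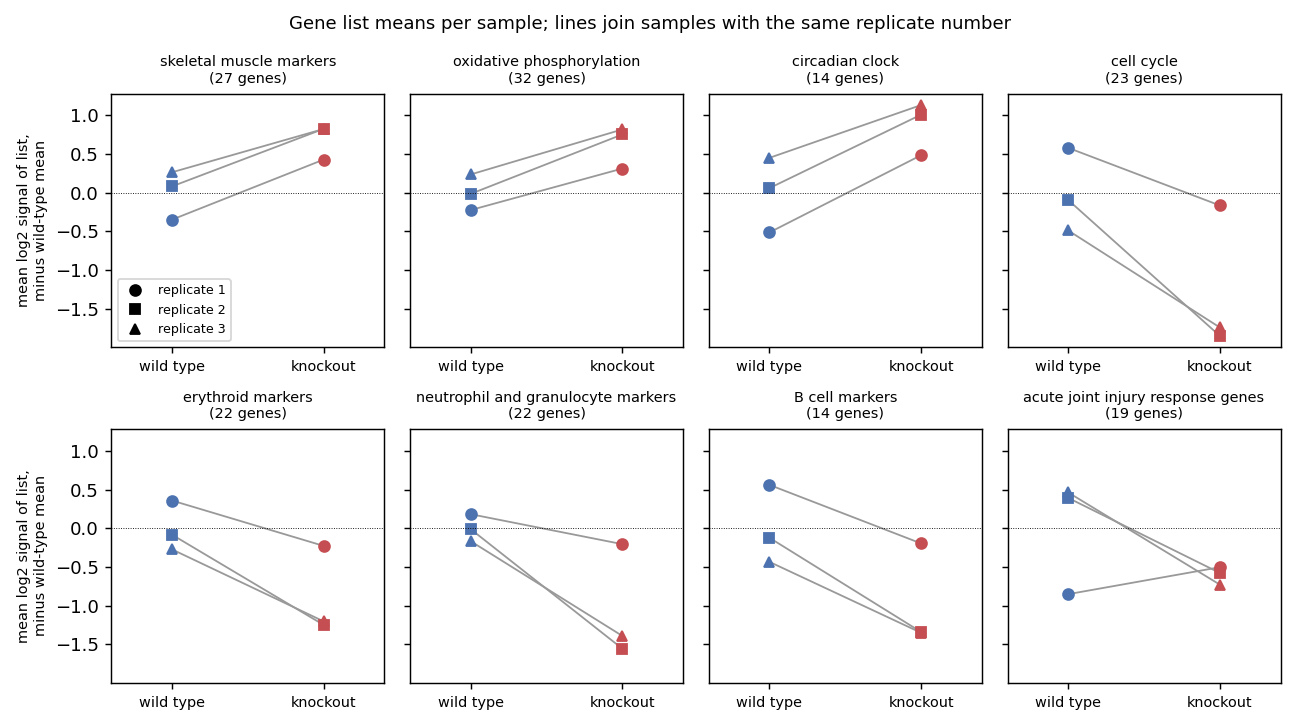
Mean log2 signal of 8 gene lists per sample, minus the wild-type mean of the list, for wild-type (blue) and Mapk9 knockout (red) samples, with lines joining samples of the same replicate number. Muscle, oxidative phosphorylation and clock lists are higher in knockout in 3 of 3 pairs, and knockout replicate 1 lies within the wild-type range in the cell cycle, erythroid and B cell lists.

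The injury, cytokine, protease and interferon lists were lower in knockout knees in camera at its preset correlation. Of 19 acute joint injury genes, 15 were lower, with a median of −0.78 (camera adjusted p = 0.00888, and adjusted p = 0.699 with an estimated correlation), and with the block 7 fell and the angiogenic gene Vegfa (0.79) rose. Examples were Inhba (−1.66), an activin subunit, the urokinase receptor gene Plaur (−1.23) and the hyaluronan synthase gene Has1 (−1.44), while Il11 was undetected in all knockout samples. The cytokine and receptor list had a median of −0.49 over 25 genes (adjusted p = 0.0220, and adjusted p = 0.699 with an estimated correlation), with 4 fallen with the block, among them the macrophage cytokine gene Osm (−1.36), the interleukin 17 receptor gene Il17ra (−1.05) and the chemokine receptor gene Cxcr4 (−1.05). The list of aggrecanases, collagenases and their inhibitors had a median of −0.30 over 21 genes (adjusted p = 0.0449 without and 0.106 with the block, and adjusted p = 0.699 with an estimated correlation), with 3 fallen (Adamts9, Adamts4 and the osteoclast protease gene Ctsk at −0.54) and the inhibitor gene Timp4 (0.87) risen with the block. Type I interferon genes had a median of −0.49 over 14 genes (adjusted p = 0.0420, and adjusted p = 0.699 with an estimated correlation), and with the block the antiviral gene Rsad2 (−2.05) and the transcription factor gene Irf7 (−1.09) fell and the nucleic acid sensor gene Zbp1 (0.57) rose. Adjusted over the list alone, 6, 2, 1 and 1 members fell without a block and 7, 4, 2 and 2 with it. With the block 28.0% of all probes passed, so counts such as 4 of 25 cytokine genes do not set a list apart. The injury list mean was 8.94, 10.19 and 10.26 in wild-type and 9.29, 9.22 and 9.07 in knockout samples, so wild-type replicate 1 lay below all knockout samples. Knockout replicate 1 lay within the wild-type range in the cytokine (9.40 against 9.04 to 9.83) and interferon lists (8.62 against 8.45 to 8.76), and knockout replicate 3 in the protease list (10.01 against 9.97 to 10.58).

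The 4 calls depended on single arrays and settings. Without wild-type replicate 2 or 3 the injury list no longer passed (adjusted p = 0.0754 and 0.110), nor did the cytokine list (0.106 and 0.136) or the protease list (0.163 and 0.238). The protease list was also lost without knockout replicate 1 (adjusted p = 0.191), and the interferon list without wild-type replicate 1 or 2 or knockout replicate 2 (0.0668, 0.0569 and 0.209). Median scaling and the authors' log2 values ended the protease call (adjusted p = 0.0574 and 0.0654) and the interferon call (0.0601 and 0.0554). Averaging over probes also ended both (0.0525 and 0.0524), and the stricter detection filter ended the injury (0.0699), protease (0.0868) and interferon (0.134) calls. With the tissue score as a covariate the interferon list did not pass (0.295), while the injury (mean −1.14, adjusted p = 9.27e-08), cytokine (−0.53, 0.000544) and protease (−0.77, 2.98e-06) lists stayed lower. These values used the preset correlation only. The score does not overlap between genotypes and shares members such as Il8rb and Mmp9 with the cytokine and protease lists. Staying lower therefore does not show that these lists are free of tissue shares.

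Bone and cell death genes completed the lower lists. Osteoblast and osteocyte markers had a median of −0.47 over 15 genes (camera adjusted p = 0.00888, and adjusted p = 0.699 with an estimated correlation), and were lower in 3 of 3 pairs. With the block 4 fell, the osteoblast transcription factor gene Sp7 (−0.66), the osteocyte gene Phex (−0.86) of phosphate balance, Ifitm5 (−0.82) and Cthrc1 (−0.74). Apoptosis and p53 genes had a median of −0.57 over 20 genes (adjusted p = 0.00583, and adjusted p = 0.699 with an estimated correlation), with 7 fallen, such as the caspase genes Casp8 (−1.17) and Casp4 (−0.86) and the survival gene Bcl2l1 (−1.10), and 1 risen with the block. Adjusted over the list alone, 0 members of either list passed without a block, and 8 osteoblast and 10 apoptosis genes fell with it, while the cyclin gene Ccng1 (0.70) rose. With the tissue score as a covariate the apoptosis list did not pass (adjusted p = 0.265), while the osteoblast list stayed lower (mean −0.39, adjusted p = 0.00554), at the preset correlation only.

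**Figure D3:**
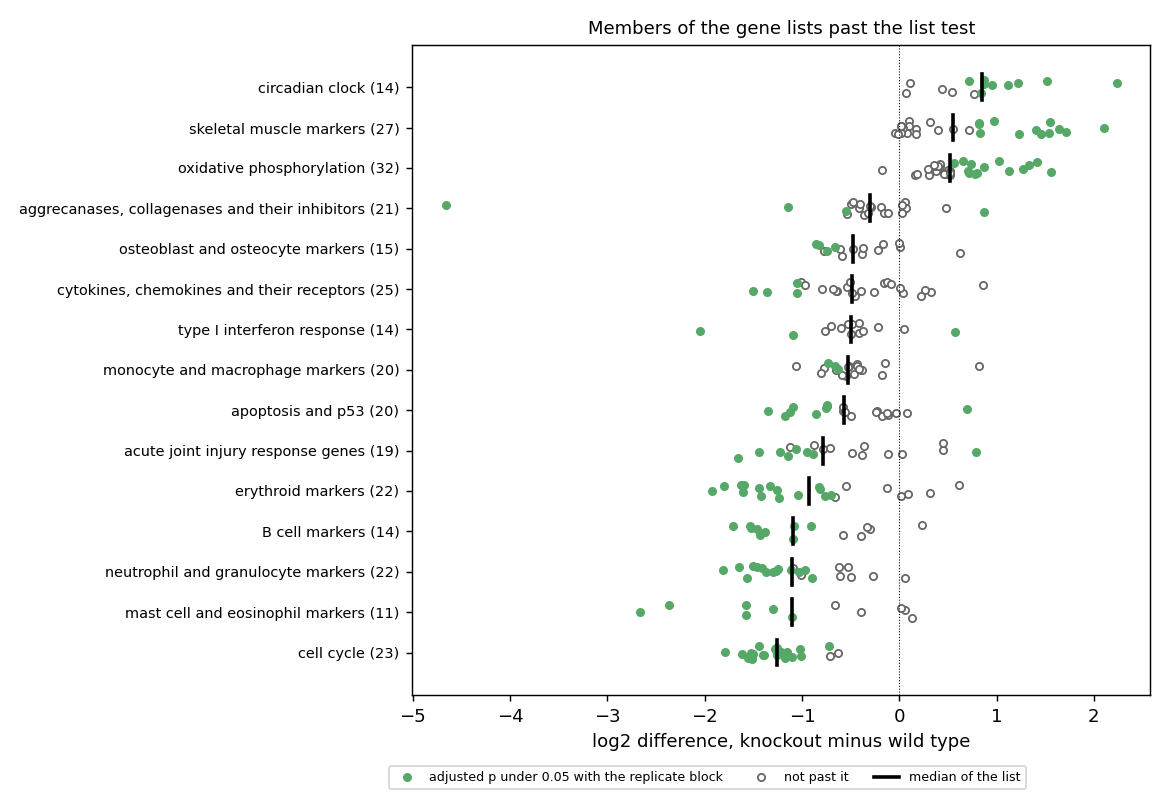
Log2 difference (knockout minus wild-type) of each member of the 15 called lists, with the number of measured members in brackets and the list median as a bar. Filled points passed adjusted p 0.05 with the replicate block, and medians run from −1.25 for cell cycle to 0.86 for circadian clock.

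Lists closest to the deleted kinase and to cartilage did not pass. JNK pathway components had a median of 0.19 over 17 genes (camera adjusted p = 0.746), with the kinase gene Map2k7 (0.64) and the adaptor gene Traf2 (0.71) higher and Map3k1 (−0.77) lower past the threshold with the block. The other MAP kinases had a median of 0.24 (adjusted p = 0.455). AP-1 and immediate early genes had a median of −0.37 over 20 genes (adjusted p = 0.128), with Fos, Fosl2 (−0.72) and the phosphatase gene Dusp2 (−1.09) lower and Jun higher past the block threshold, and this list passed without wild-type replicate 1 (adjusted p = 0.00642) and with the tissue score as a covariate (0.0109). NF-kB genes had a median of −0.34 (adjusted p = 0.128) and passed with array weights (0.0461) and no filter (0.0249). Cartilage matrix and chondrocyte markers had a median of −0.14 over 20 genes (adjusted p = 0.702), with 0 members past the threshold in either fit, and hypertrophic chondrocyte markers one of −0.34 (adjusted p = 0.164; 0.0109 with no filter). Genes flanking Mapk9 on chromosome 11 had a median of −0.14 over 20 genes (adjusted p = 0.420), with Trim11 (−1.17) lower and the autophagy receptor gene Sqstm1 (0.72) higher past the block threshold.

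In all 15 of 39 lists were called, 3 higher and 12 lower. With an estimated correlation 0 were called (lowest adjusted p = 0.699), and 0 by fry, a self-contained test of a shift in 1 direction (lowest adjusted p = 0.193, with 8 lists at an unadjusted p under 0.05), against 0 lists at an unadjusted p under 0.05 for camera with an estimated correlation.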

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

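The tissue score as a covariate, the replicate block with the authors' table and the repeats of the block fit were chosen after the result was seen; the other settings were planned. Signal over background limits the values: probes near the lowest detected signal have compressed differences, and an undetected group gives only a bound. Scaling to the median moved the median of all probes by −0.10. Across all settings the main results kept their value or side of the threshold in 64 cases, moved in 29, became stronger in 10 and weaker in 7; list results did so in 753, became stronger in 44, weaker in 58 and changed direction in 39, and named genes in 1740, 423, 38 and 34. List values here are mean log2 differences. Except where stated, the cause was not tested.

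With the replicate block 3888 genes passed in place of 7, all 7 included (4146 with the random replicate block, 3271 with the replicate block and the authors' table). Mapk9 ILMN_2591066 passed at −1.67 with either block and at −1.73 with the block and the authors' table. Of the lists, the block ended the protease call and added the T and NK call; among the lists and genes the report names it changed no other call than those printed there, and it ended no gene call. The Wnt list kept its mean of −0.0523 with the block, and only the direction of its test turned (adjusted p = 0.943), as at −0.0800 with the block and the authors' table, where Mmp3 ILMN_2753809 was −0.0262.

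Genes without the block numbered 12 with an offset of 50 (6 higher), 11 with median scaling (6 higher, against 2 of 7 with quantile normalization), 12 with the authors' normalized table or the series matrix values (5 higher), 11 with trend and robust, 9440 with array weights, 2 with no filter, 0 with the strict filter (limma, 3507 probes at an unadjusted p under 0.05), 3 against a fold of 1.5 and 2 with 1 probe per gene. The strict filter drops any probe undetected in 1 genotype, such as those of Nnmt, Adamts9, LOC380706, Myh8 and Mapk9 ILMN_2716527. For these its count of 0 is no test. Array weights stopped before their convergence tolerance was reached. Without the block they were 8.07 for wild-type replicate 2 and 6.41 for knockout replicate 3, against 0.17 to 0.56 for the other arrays. Fits with these weights thus rest largely on 1 array per genotype. Lists numbered 23 with no filter, and 0 with an estimated correlation or by fry, in either fit; a further option of fry for shifts in mixed directions had a lowest adjusted p of 0.00282. With the block, genes numbered 1961 with no filter (1165 higher, 790 lower), 7631 with array weights (3457 higher, 4062 lower) and 355 against a fold of 1.5 (286 higher, 68 lower). With median scaling and the block 1335 were higher and 1916 lower, so the balance of directions depends on the setting. Mapk9 ILMN_2591066 passed at −1.45 with no background correction, −1.60 with an offset of 50, −1.73 with the authors' table or the series matrix values, −1.67 with trend and robust and −1.59 with array weights. Mapk9 ILMN_2716527 did not pass against a fold of 1.5 (−2.21, a stricter question) or with the tissue score (−2.07).

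Directions changed as follows; the direction of a list is that of its test against all other genes. Median scaling: Mapk8 −0.0209 (ILMN_1239233) and −0.065 (ILMN_1214761), Mmp3 ILMN_2753809 −0.0764. Authors' table and series matrix values: Mmp3 ILMN_2753809 −0.0262. Array weights: Mmp3 −0.28 (ILMN_2899041) and −0.67 (ILMN_2753809), tendon list 0.11, Wnt 0.0205, oxidative stress −0.0966. Strict filter: JNK pathway 0.00454, Wnt 0.102. The muscle, erythroid, neutrophil and B cell lists make up the tissue score, so values of these lists and their genes with it are fixed by construction and say nothing about them. Tissue score as a covariate, genes: Acan 0.0362, Jun −0.37, Mapk8 −0.66, Mmp13 −0.26, Mmp3 −1.08 and −0.77, Retnlg 0.16, Rora −0.16, Gata1 0.11, Cd79b 0.15, Faim3 0.43, Blk 0.36, Bcl2l1 0.14, Irf7 0.35, Ifit2 0.0678, Nkg7 0.73, Il7r 0.24. Tissue score as a covariate, lists: JNK pathway −0.0531, NF-kB 0.0803, cartilage 0.0887, neutrophil −0.00034, monocyte 0.0188, erythroid 0.0991, B cell 0.30, T and NK 1.08, smooth muscle −0.42, type I interferon 0.19, type II interferon 0.99, cell cycle 0.38, clock 0.0355, glucocorticoid −0.13, heat shock −0.13, hypoxia −0.18. The means of the clock and neutrophil lists with the tissue score, of JNK pathway with the strict filter and of oxidative stress with array weights kept their sign, and only the direction of the test turned.

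Leaving out 1 sample at a time gave 0 to 4698 genes (0 without knockout replicate 2; limma, 2625 probes at an unadjusted p under 0.05), and leaving out 1 pair with the replicate block gave 1694 to 5465 (without pairs 3 and 1). Ranges were −2.28 to −2.11 for Mapk9 ILMN_2716527 and −1.80 to −1.56 for ILMN_2591066. They included both signs for Mapk8 ILMN_1214761 (−0.12 to 0.35), for Mmp3 ILMN_2704576 (−0.59 to 0.39), ILMN_2753809 (−0.48 to 0.40) and ILMN_2899041 (−0.31 to 0.74), and for the lists Wnt (−0.18 to 0.0666), adipocyte (−0.49 to 0.0470), cartilage (−0.16 to 0.0241), glucocorticoid (−0.0121 to 0.38), hypoxia (−0.0589 to 0.11), oxidative stress (−0.27 to 0.0560), smooth muscle (−0.0949 to 0.19), synovial (−0.38 to 0.15), tendon (−0.25 to 0.0757) and type II interferon (−0.55 to 0.38).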

Other observations

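Stress and signalling lists did not pass, although members of them, like 28.0% of all probes, passed with the replicate block. Of 17 heat shock genes 6 rose with the block, among them the regulator gene Hsf1 (0.67) and the chaperone genes Hspb8 (0.79) and Cryab (0.77), and 2 fell, Dnajb1 (−0.88) and Hsp90aa1 (−0.59), with a list median of 0.28 (camera adjusted p = 0.0642; 0.0159 without wild-type replicate 3 and 0.0382 without knockout replicate 1). Of 16 glucocorticoid response genes 4 rose with the block, such as the transcription factor genes Zbtb16 (1.41) and Klf9 (0.81), and 2 fell, Lcn2 (−1.25) and Cebpd (−0.67), with a median of 0.12 (adjusted p = 0.369; 0.0498 without wild-type replicate 3). The unfolded protein list had a median of −0.41 (adjusted p = 0.109; 0.0105 with no filter) with Chac1 (1.37) higher and Asns (−0.81) and Sdf2l1 (−0.73) lower with the block. Ribosomal protein genes had a median of −0.17 (0.0630) and passed with no background correction (0.0179), an offset of 50 (0.0421), trend and robust (0.0111), array weights (0.0208), no filter (0.000724), the strict filter (0.0328) and averaging over probes (0.0235). Heat shock genes passed with no background correction (0.0494), trend and robust (0.0423), array weights (0.00459), no filter (0.0109) and averaging over probes (0.0286). Hypoxia and glycolysis genes had a median of 0.21 (0.687), TGF-beta genes −0.14 (0.655), Wnt genes −0.06 (0.768), oxidative stress genes −0.08 (0.768) and type II interferon genes −0.11 (0.768). The type II interferon list was lower without knockout replicate 1 (adjusted p = 0.0337) and higher without knockout replicate 2 (0.0164).

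Other tissues of the joint did not pass as lists in the planned fit. Endothelial markers had a median of −0.28 (camera adjusted p = 0.0648; 0.00183 without wild-type replicate 1 and 0.0266 without knockout replicate 3), with the adhesion genes Selp (−0.96) and Cdh5 (−0.60), Vwf (−0.83) and Mmrn1 (−0.79) lower with the block. Osteoclast markers had a median of −0.43 (0.102; 0.0336 without wild-type replicate 3), nerve and Schwann cell markers −0.51 (0.236; 0.0331 without wild-type replicate 1), synovial lining markers −0.04 (0.579; 0.00316 without wild-type replicate 1) and adipocyte markers −0.28 (0.722; 0.0219 without wild-type replicate 1). Tendon markers had a median of −0.12 (0.687) and smooth muscle markers −0.09 (0.722, with a mean of 0.06). With the tissue score as a covariate, chosen after the result was seen, synovial (mean −0.78, adjusted p = 2.17e-08), adipocyte (−0.90, 0.000141), endothelial (−0.39, 0.00212), tendon (−0.53, 0.0130) and smooth muscle lists (−0.42, 0.0294) were lower, as were the Wnt (0.00450), TGF-beta (0.0131) and oxidative stress lists (0.000984). These values too used the preset correlation only. The endothelial list also passed with no background correction (0.0454), no filter (0.00129) and the strict filter (0.0213), and the osteoclast list with no filter (0.0170).

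All tests from here on were chosen after the result was seen. The 6 samples make 10 splits of 3 against 3, too few for a share under 0.05: 1 of the 10 gave as many probes without the block (7, highest other 0) and 3 gave as many lists (15, highest other 23). The other splits called 3 to 23 lists, so camera at its preset correlation also called lists under groupings that mix the genotypes. The split with 23 lists sets wild-type replicate 1 with knockout replicates 2 and 3. What lies behind these calls was not tested. Of the 4 splits that part all 3 pairs, 1 gave as many probes with the block (4826, highest other 0), again too few.

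Here marrow lists are the erythroid, neutrophil and B cell lists, although where in the knee these cells lay was not measured. They were lower and the muscle list was higher in knockout knees. Different shares of marrow and muscle among the dissected knees may account for this: wild-type replicates 3 and 1, which share a genotype, differed along the same genes as the knockout mean and wild-type replicate 2, contrasts with no array in common (r = 0.471 across 12760 genes; 0.199 and 0.412 for the other wild-type pairs against the third), though this does not tell tissue shares from another structure of the samples. A lower share of marrow alone would raise muscle and other tissues alike, but muscle rose over the mean of other tissues by 0.76 (SE 0.10). Net of genes of the same signal the tissue score differed by 1.65 (SE 0.63, against 1.66 in full). Quantile normalization had already made such genes alike between arrays, so this cannot decide about a signal-dependent offset between arrays. An effect of the genotype on these tissues stays open and was not tested.

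Single probes of Nnmt and Sparc dropped much further than their other probes, with a smallest difference between probes of −3.24 (log2), which may come from a sequence variant or transcript form under the probe. For Mapk9 the other detected probe was also lower (−1.67), which argues against a change at 1 probe alone. Adamts9 and LOC380706 have 0 other detected probes, so the same explanation stays open for them. A segment of chromosome 11 carried along with the knockout allele is argued against for Nnmt, which lies on chromosome 9. Whether the genotypes differ elsewhere in the genome was not tested. For Sparc, on chromosome 11 and 49 tested genes from Mapk9, such a segment stays open. Of nearby genes with several probes 7.69% (2 of 26) disagreed between probes, against 4.86% elsewhere (158 of 3253), too few to tell. Sparc itself is among the 2, so this count is not independent of the pattern it was meant to test.

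Chromosome 11, which carries Mapk9, held 19 of the 100 genes of smallest p without the block, Mapk9 left out, against 8.35% of all placed genes (Fisher's exact p = 0.000695, which takes genes as independent; highest of the other splits 12). The size of 100 was 1 of several tried: 7 of 20, 14 of 50, 30 of 200 and 55 of 500 genes lay there, and of 100 genes 16 with the block and 17 with the tissue score as a covariate. Whether a genomic segment carried along with the Mapk9 knockout allele accounts for part of these changes stays open. Myh8 lies 144 tested genes from Mapk9, further than the 100 nearest genes. Its second probe differed by only 0.37, so a difference at a single probe stays open for it too. The 100 genes nearest Mapk9 did not reach an unadjusted p under 0.01 in limma more often than others. The ratio was 0.463, 0.907 and 0.749 with 3 ways to place genes, covering 87.1%, 65.8% and 45.6% of them. This comparison used the brightest probe of each gene, so a drop at another probe, as in Sparc, did not enter it. Chromosome 9, for which no segment was proposed, held 13 of the 100 genes of smallest p (5.73% of placed genes). An effect of JNK2 on these genes stays open and was not tested.

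The clock list was higher in knockout knees. More skeletal muscle in the sample stays open as an explanation. The list mean went from 0.88 to 0.0355 with the tissue score as a covariate (camera adjusted p = 0.995). That score also holds the marrow lists, and between genotypes the marrow score differed by −0.97 and the muscle score by 0.69. The drop therefore cannot tell more muscle from less marrow. That score does not overlap between the genotypes, so the covariate may also remove an effect of genotype. A different time of day at collection stays open: Arntl and Clock, whose phase is opposite to that of Dbp (0.87), differed by a mean of 0.0931. An effect of JNK2 on the clock stays open and was not tested.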
